A study of Mesocricetus auratus with 10 samples.

How the data were processed

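Liver RNA of 10 male golden hamsters on the high fat diet and 1 pool of liver RNA from 10 hamsters on the standard diet was measured on 20 custom Agilent arrays of 2 colours. Per the labels' protocols, RNA was extracted with a column kit and 100 ng was converted to Cy3- or Cy5-labelled cRNA with a whole-transcript labelling kit. Each HFD sample was hybridised against the pool in both dye orientations, as the labels state for each sample, and the dye of each RNA on an array was read from the array's own name as deposited. Every sample's column of the authors' log2 ratios correlated across genes with the red over green ratio of its array with HFD in Cy5 at r between 0.604 and 0.901, and with that of its array with HFD in Cy3 at r between -0.942 and -0.789, which shows the 2 arrays of each sample in opposite orientations. Which of the 2 holds HFD in Cy5, and so the direction of all ratios, rests on the array names. The arrays lay on 7 slides and were scanned in 3 sessions, each holding only this 1 comparison. The 10 HFD animals are the replicates, numbered as in the labels.

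The deposited spot intensities, mean pixel brightness and median local background in green and red, were made with the Agilent Feature Extraction software, per the file headers. The same deposited tables hold processed intensities, which the software had background-subtracted and dye-normalised by LOWESS, per the file headers, and their red over green ratio on the log10 scale, per the file headers. The log10 ratio entered none of the values given here. The authors also deposited log2 ratios per probe and sample. The submitters' processing notes name limma for these, and the background method, the normalisation and the way the 2 arrays of a sample were combined are not given in the sources used here. Set against the scanner values, and with the dyes as read from the array names, these columns run as HFD over STD pool on a log2 scale. Their medians for animals 1 to 10 were -0.000128, -0.0145, -0.000492, -0.00171, 0.0185, -0.0122, -0.00991, 0.0075, -0.0012 and -0.0103. Their correlation across genes with the ratios computed here lay between 0.92 and 0.973 per animal, with slopes between 0.999 and 1.39, so that their centring and exact scale stay unknown.

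Each array held 170327 spots, 165353 of them not controls, and no spot was saturated. Between 77.2% and 97.7% of probes were well above background in the HFD RNA of an array, and between 76.7% and 96.7% in the pool. Median green signal per array lay between 102.1 and 267.8 intensity units over a background of 25 to 59, and median red signal between 164.2 and 713.7 over 47 to 87. The number of arrays limits the precision of the values.

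Intensities were background-corrected with normexp (offset 50) and normalised within each array by loess in limma 3.58.1 under R 4.3.3, with control spots and outlier spots at weight 0 in loess and left out afterwards. Spots of a probe were averaged. Ratios were turned to HFD over STD pool on every array, and the 2 dye-swapped arrays of a sample were averaged to 1 replicate. A probe was kept when it was well above background in the HFD RNA or in the pool on at least 10 of the 20 arrays and had a value on all of them. The brightest such probe stood for its gene. Gene names are those of the array's design. 76.8% of the tested names occur among the symbols of the RefSeq annotation of the hamster assembly BCM_Maur_2.0, and the others were kept as in the files. Probes with a descriptive name (336) were left out, and unnamed transcripts were tested apart.

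The mean log2 ratio of each gene was tested against 0 with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment over the 13827 genes and a threshold of 0.05. The pool is the control's own RNA, and the test takes this 1 RNA as a fixed reference without error. The 49 gene lists, 38 of pathways and 11 of cell types, were fixed before the data were examined, and 48 had at least 5 measured genes. The list of pancreatic and intestinal genes had 2 and was not tested. Lists were tested with camera (preset correlation 0.01) on the 10 ratios, with camera at an estimated correlation and fry beside it. Called genes of a list were counted over all genes tested and again adjusted over the list alone. Pearson and Spearman correlations between list means carry permutation p from 100000 resamples at 10 animals, and exact ones at fewer.

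The genes named in the text follow a rule fixed in advance. It takes the 12 highest and 12 lowest mean ratios among called genes with a proper gene name, the same sign in all animals and a probe well above background in both RNAs on at least 10 arrays. For each described list it adds up to 4 members, the 2 with the smallest p in the list's direction and the 2 with the largest change among the remaining called ones. Genes outside the rule are marked as such. Some of the genes so taken are not reported here.

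The test was tried on simulated ratios for the 13827 genes with 67, 67 and 66 genes changed by 0.25, 0.5 and 1 on the log2 scale. It recovered 86.6% of the first and 100% of the others, with 10 false calls among 201. The sign-flip test, whose smallest p is 0.00195, recovered 0% of them, since so few changed genes cannot pass the adjustment at that p. Camera called the 1 list that was shifted and 0 of the others. The noise was drawn independently for each gene, with no correlation between genes, no error shared through the pool and no array effect. The simulation therefore says nothing about false calls from these sources.

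Alternatives fixed in advance were no background subtraction, the software's processed signals without loess, quantile scaling of average brightness, the authors' log2 ratios, no filter and a strict filter on dim probes, the mean of all probes of a gene, arrays of 1 orientation, array-level fits with a dye term and the animal or the slide as a random block, eBayes with a trend and robust variance, an exact sign-flip test, camera with an estimated correlation, fry, and leaving out each animal. Chosen after the arrays were examined were the fits without 6 arrays, in animals 1 to 4 or 5 to 10, and within the scan sessions. The fit without 6 arrays was made on single arrays with a dye term and the animal as a random block. Figures were drawn with matplotlib 3.10.9.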

Results

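Liver RNA of 10 male golden hamsters (Mesocricetus auratus) fed a high fat diet (HFD), a model of fatty liver, was compared with 1 pool of liver RNA from 10 hamsters fed a standard diet (STD). Each HFD liver was hybridised against the pool on 2 arrays with the dyes exchanged, so that 20 arrays gave 10 biological replicates. The array carried 116452 probes, of which 67053 bore a gene name from the array's design and 49063 belonged to unnamed assembled transcripts. After the filter on dim probes, 13827 named genes were tested, each by its brightest probe. Values are mean log2 ratios of HFD liver over the STD pool ± SD between animals (n = 10), with adjusted p from limma, two-sided. The number of arrays limits the precision of these values.

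The question of the main comparison was which liver genes differ in expression between the diets. Sterol genes stood near the top and at the bottom of the ranking by ratio. ABCG5, which with ABCG8 forms the exporter of sterols into bile, rose 7.59-fold (2.92 ± 0.23), and FDFT1, the squalene synthase of cholesterol synthesis, fell 4.58-fold (-2.19 ± 0.36). WSCD2 (3.0 ± 0.16), FER1L4 (2.74 ± 0.43), the annexins ANXA3 (1.94 ± 0.48) and ANXA2 (1.82 ± 0.49), LIX1L (1.83 ± 0.10) and CYP4A10 (1.80 ± 0.24), a fatty acid omega-hydroxylase, were among the 12 genes that rose most, counting genes with the same sign in all animals and a probe detected in both RNAs. The carboxylesterase genes CES1D (2.24 ± 0.27) and CES1F (1.77 ± 0.30), FST (1.56 ± 0.67), which encodes the activin-binding protein follistatin, USP18 (1.56 ± 0.31), an interferon-induced protease, and INMT (1.56 ± 0.31) completed them. Among the 12 that fell most, SQLE (-1.61 ± 0.13) and IDI1 (-1.58 ± 0.12) also encode enzymes of cholesterol synthesis. LPIN1 (-1.61 ± 0.77), a phosphatidate phosphatase of triglyceride synthesis, the mitochondrial carrier gene SLC25A47 (-1.67 ± 0.52), SERPINF1 (-1.64 ± 0.31), the lipocalin gene LCN14 (-2.00 ± 0.92), the serum amyloid gene SAA3 (-1.56 ± 0.84) and CYP4B1 (-1.53 ± 0.52) fell as well. SQLE and LPIN1 were well above background in the HFD RNA on only 12 and 15 of the 20 arrays, so that their sizes and ranks are uncertain. Each gene named in this paragraph had the same sign in 10 of 10 animals, and their adjusted p lay between 1.08e-13 (WSCD2) and 5.32e-05 (SAA3).

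Across all named genes, 4343 were higher and 3994 lower in HFD liver at an adjusted p under 0.05, 60.3% of those tested. Most changes were small, with a median size of 0.194 on the log2 scale. At least 2-fold changes were found for 45 higher and 58 lower genes. These counts were 104 and 113 with the scanner software's processed signals, and 85 and 92 with the authors' own log2 ratios, but 29 and 34 with the mean of all probes of a gene. Of the genes called, 4355 had the same sign in all 10 animals. The unnamed transcripts gave 8514 higher and 12026 lower of 41891 tested. Because the STD animals were measured only as a pool, the test leaves out their own spread and takes the pool as a fixed reference without error. Anything peculiar to this 1 pool enters all 10 ratios. The adjusted p thus measures how far the HFD animals agree against this pool.

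The 6 arrays with HFD RNA in Cy3 of animals 5 to 10 stood apart from the other 14. Without them, a setting chosen after the arrays were examined, 3448 genes were higher and 2529 lower, with 50 and 40 genes at least 2-fold. This fit, which also gave the calls and list means on the 14 arrays below, used single arrays with a dye term and the animal as a random block. In that form all 20 arrays gave 4443 higher and 4076 lower genes. They called 3 lists higher, cell cycle no longer among them, and 11 lower, against 6 and 13 on the 14. Interferon response and autophagy were among the 3, and the remaining list, not named here, was not called in the main fit. No list but this could owe a higher call on the 14 arrays to the form of fit alone. The 11 lower lists were those of the main fit. Lists called lower only on the 14 arrays were thus not called on 20 arrays in the same form. Of the 8337 genes called on 20 arrays, 5430 were called with the same sign on these 14 and 3 with the opposite sign. All 14 gene lists called on the 20 arrays were called in the same direction on the 14, by camera with the preset correlation. With an estimated correlation 13 of the 14 calls on the 20 arrays were lost.

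Probes for the same gene did not always go the same way. Of 6945 called genes with further probes, 1593 (22.9%) had at least 1 probe called in the opposite direction. CES1D was such a gene, with 2 further probes higher and 4 lower. ZBTB5 (-1.70 ± 0.20), ENHO (-1.68 ± 0.20), which encodes adropin, and PPM1F (-1.61 ± 0.17) ranked among the 12 that fell most by their brightest probe. Of their further probes only 1 of 4, 1 of 2 and 1 of 4 fell. Their brightest probes had nearly the same ratio in each animal, such as -1.33, -1.32 and -1.32 in animal 3. In animal 5 the ratios were -2.01, -2.01 and -1.91. Whether these probes report 3 separate genes was not tested, so they may not be 3 separate changes. Of the genes named below, ABCA1 had 9 of 25 further probes called in its direction, CTSB 3 of 8 and IL1B 1 of 3. Further probes that agreed in direction gave smaller changes for several genes, with medians of 1.09 for WSCD2, -0.58 for LPIN1, 0.68 for STEAP4, 0.38 for LPL, 0.19 for PDK2 and -0.32 for CXCL9.

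**Figure D1:**
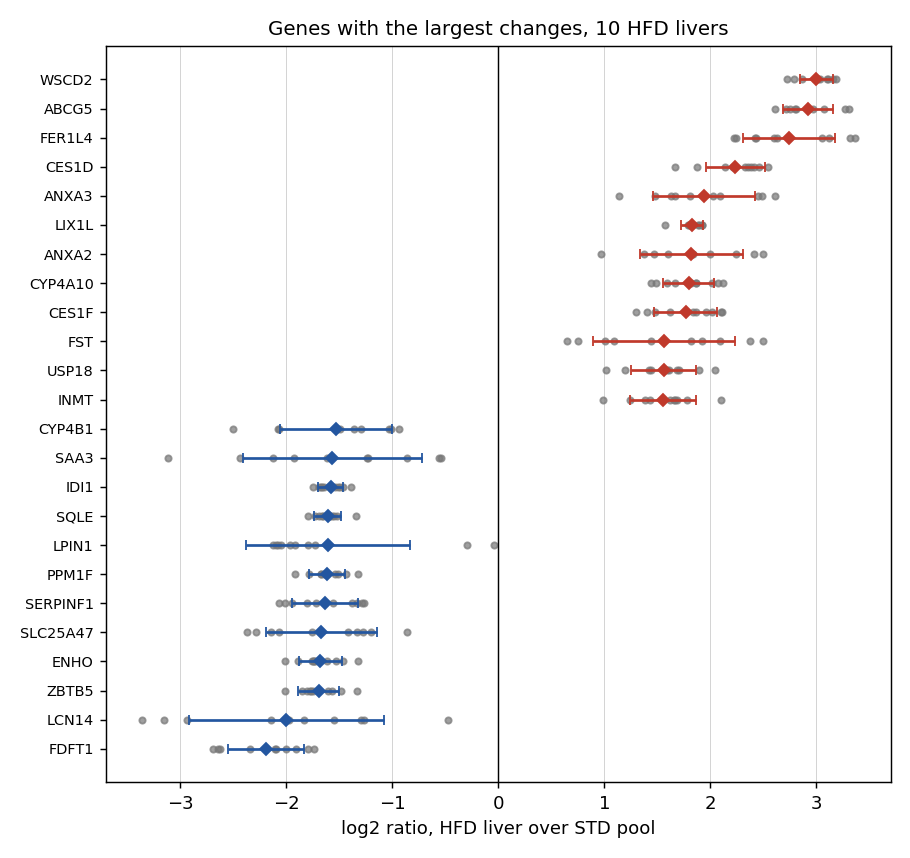
Log2 ratio of HFD liver over the STD pool for the 12 genes that rose most and the 12 that fell most among genes with the same sign in all animals and a probe detected in both RNAs. Grey points are the 10 animals, diamonds the mean and bars the SD, and all animals lie on the same side of 0 for each gene, from a mean of 3.0 for WSCD2 to -2.19 for FDFT1.

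Cholesterol synthesis was the gene list with the clearest shift: 19 of its 23 measured genes fell and 1 rose (mean log2 ratio -0.59 ± 0.02, below 0 in 10 of 10 animals, camera adjusted p = 1.10e-08, adjusted p = 0.00301 with an estimated correlation). It was the one list of the 14 called whose call held with an estimated correlation between genes. The size depends on the processing, with a mean of -0.92 by the software's processed signals and -0.87 by the authors' log2 ratios. FDPS (-1.25 ± 0.07), which makes farnesyl diphosphate, fell together with FDFT1, SQLE and IDI1. INSIG1 (-1.27 ± 0.22), a regulator of sterol sensing and no enzyme, fell too and was named after its value was seen. In the list of bile acid and sterol transport, 5 of 18 genes rose and 8 fell (mean log2 ratio 0.14 ± 0.05, above 0 in 10 of 10 animals, camera adjusted p = 0.780). ABCG5, ABCG8 (1.16 ± 0.19) and ABCA1 (0.51 ± 0.18), which exports cholesterol to lipoproteins, rose, whereas the bile acid importer SLC10A1 (-0.58 ± 0.22) fell. The median of this list and its camera direction were below 0 while its mean was above.

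**Figure D2:**
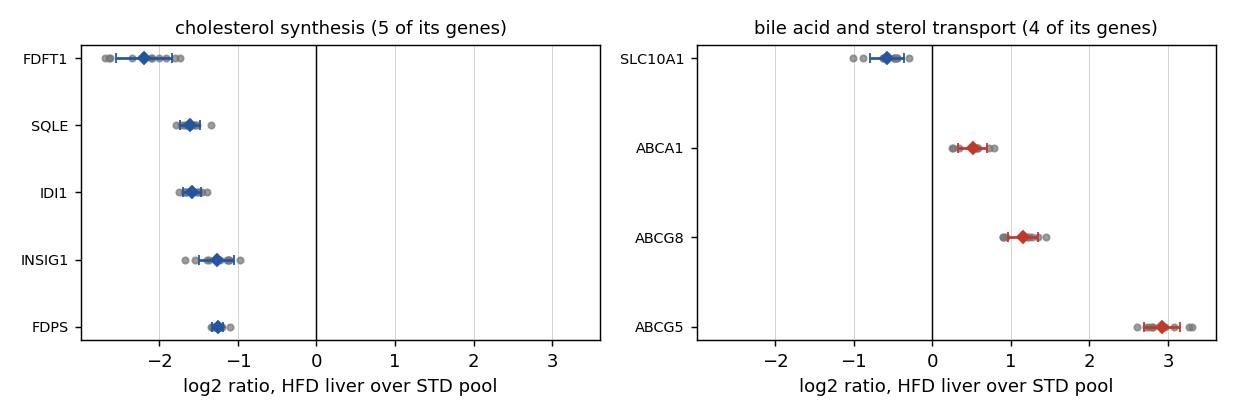
Log2 ratios of the genes named in the text from the lists for cholesterol synthesis (left) and bile acid and sterol transport (right). Grey points are the 10 animals, diamonds the mean and bars the SD. All 5 genes shown from the synthesis list lie below 0, from -2.19 for FDFT1 to -1.25 for FDPS. Among them is INSIG1, a regulator and no enzyme, named after its value was seen. ABCG5 and ABCG8 stand above the other transport genes at 2.92 and 1.16.

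Bile acid synthesis and conjugation had 8 lower and no higher genes of 12 (mean log2 ratio -0.33 ± 0.15, below 0 in 10 of 10 animals, camera adjusted p = 0.00694, adjusted p = 0.561 with an estimated correlation). CYP8B1 (-0.70 ± 0.21), the sterol 12-alpha-hydroxylase, AKR1D1 (-0.97 ± 0.46), CYP39A1 (-0.78 ± 0.36) and AMACR (-0.33 ± 0.12) fell. On the 14 arrays the mean of this list was -0.18, and on arrays with HFD in Cy3 alone its call was lost (adjusted p = 0.0561) at a mean of -0.38. Apolipoproteins and lipoprotein metabolism had 5 higher and 6 lower genes of 17 (camera adjusted p = 0.982). APOA4 (0.73 ± 0.26), APOE (0.69 ± 0.10) and APOA2 (0.66 ± 0.08) rose, the last 2 by 1.23 and 1.17 on arrays with HFD in Cy5 but 0.15 and 0.15 on the others.

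Fatty acid synthesis genes moved in both directions: 10 of 23 rose and 7 fell (mean log2 ratio 0.07 ± 0.17, above 0 in 7 of 10 animals, camera adjusted p = 0.982). SREBF1 (1.27 ± 0.28), the transcription factor of lipogenesis, and THRSP (1.02 ± 0.26) rose, whereas ACLY (-0.94 ± 0.15), which makes cytosolic acetyl-CoA, and the desaturase gene FADS1 (-0.78 ± 0.19) fell. Triglyceride synthesis and secretion was lower, with 10 of 14 genes down and 2 up (mean log2 ratio -0.32 ± 0.10, below 0 in 10 of 10 animals, camera adjusted p = 0.0165, adjusted p = 0.342 with an estimated correlation). This call was also lost on arrays with HFD in Cy3 alone (adjusted p = 0.168) and in animals 5 to 10 (0.0517), at means of -0.32 and -0.38. Besides LPIN1, TM6SF2 (-0.82 ± 0.25), AGPAT3 (-0.49 ± 0.10) and GPAM (-0.71 ± 0.61), the mitochondrial glycerol-phosphate acyltransferase, fell. GPAM was above 0 in 2 of 10 animals. The lipid droplet list was not called, with 3 of 17 genes higher and 7 lower (mean log2 ratio -0.13 ± 0.13, below 0 in 8 of 10 animals, camera adjusted p = 0.50). The droplet coat genes went opposite ways, PLIN3 (0.84 ± 0.28) up and PLIN2 (-1.01 ± 0.59) down, and HSD17B13 (-1.02 ± 0.35) and FITM2 (-0.35 ± 0.12) fell. Of the fatty acid uptake and binding list, 1 of 16 genes rose and 7 fell (mean log2 ratio -0.19 ± 0.05, below 0 in 10 of 10 animals, camera adjusted p = 0.0896). LPL (0.81 ± 0.19), lipoprotein lipase, was the gene that rose, while DBI (-0.96 ± 0.18), an acyl-CoA binding protein, and the acyl-CoA synthetase genes ACSL5 (-0.96 ± 0.50) and ACSL1 (-0.54 ± 0.29) fell. On the 14 arrays this list was called lower, at a mean of -0.14 (adjusted p = 0.0289), and on the 20 arrays adjusted p was 0.357 with an estimated correlation.

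Genes of fatty acid oxidation were mostly lower. Of the PPAR alpha targets, 18 of 20 fell and 1 rose (mean log2 ratio -0.33 ± 0.11, below 0 in 10 of 10 animals, camera adjusted p = 3.85e-05, adjusted p = 0.357 with an estimated correlation). EHHADH (-1.02 ± 0.19) of the peroxisomal pathway and ANGPTL4 (-1.15 ± 0.37) fell, as did PLIN2, and CYP4A10 was the target that rose. In the peroxisomal and microsomal oxidation list, 14 of 21 genes fell and 1 rose (mean log2 ratio -0.20 ± 0.13, below 0 in 10 of 10 animals, camera adjusted p = 0.00694, adjusted p = 0.690 with an estimated correlation), among them CROT (-0.75 ± 0.55). In mitochondrial fatty acid oxidation and ketogenesis, 14 of 23 fell and 6 rose (mean log2 ratio -0.22 ± 0.10, below 0 in 10 of 10 animals, camera adjusted p = 0.0165, adjusted p = 0.748 with an estimated correlation). The members ECI2 (-0.80 ± 0.16), ACADM (-0.64 ± 0.26), DECR1 (-0.59 ± 0.38) and ACAA2 (-0.48 ± 0.06) fell. On arrays with HFD in Cy3 alone the calls of the peroxisomal and the mitochondrial list were lost (adjusted p = 0.131 and 0.138), at means of -0.21 and -0.22. The means of these 3 lists on the 14 arrays were -0.28, -0.12 and -0.15. The mitochondrial respiratory chain list was not called (mean log2 ratio -0.12 ± 0.14, below 0 in 8 of 10 animals, camera adjusted p = 0.364), although 16 of 29 genes fell and 9 rose. On the 14 arrays its mean was 0.02 and its camera direction upward. UQCRQ (-0.50 ± 0.27), COX5B (-0.45 ± 0.26) and NDUFA4 (-0.50 ± 0.31), all subunits of the chain, fell on the 20 arrays.

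**Figure D3:**
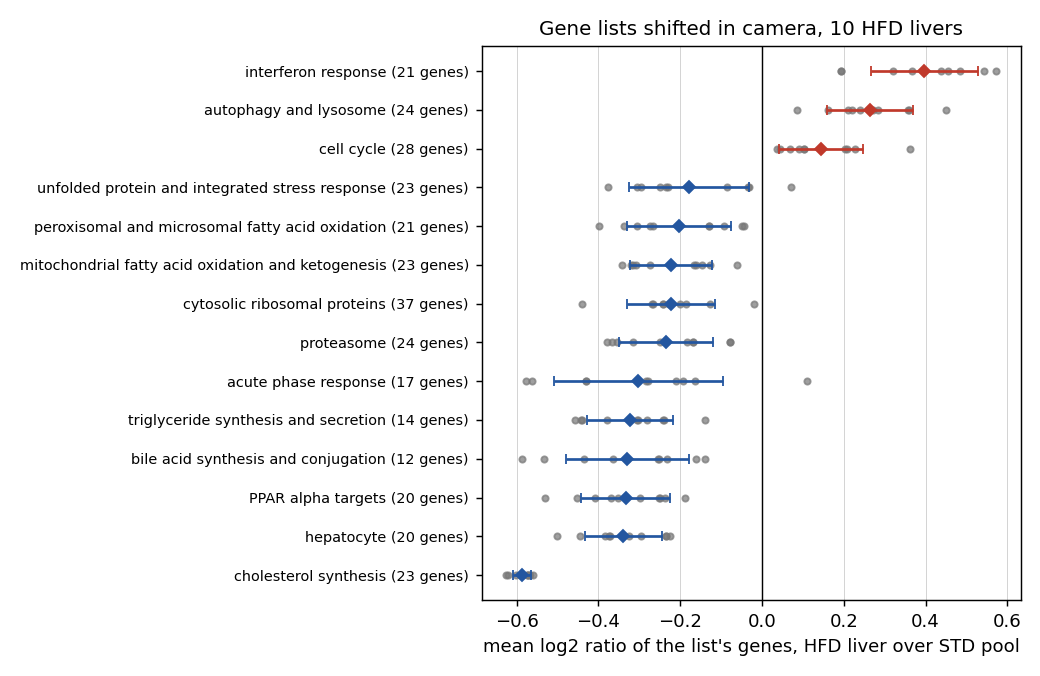
Mean log2 ratio of HFD liver over the STD pool for the 14 gene lists called by camera with a preset correlation of 0.01. Grey points are the list means of the 10 animals, diamonds their mean and bars the SD. Interferon response is highest at 0.40 and cholesterol synthesis lowest at -0.59, with the narrowest spread between animals.

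Glucose genes moved apart. PCK1 (-1.52 ± 0.46) and G6PC (-0.81 ± 0.41), enzymes of gluconeogenesis, fell, whereas TPI1 (0.73 ± 0.11), PDK2 (0.74 ± 0.18) and PPP1R3C (0.77 ± 0.33), a glycogen-targeting phosphatase subunit, rose. UGP2 rose by its brightest probe (0.98 ± 0.20), and none of its 8 further probes was called. Neither gluconeogenesis and glycogen (6 of 16 up, 7 down, camera adjusted p = 0.752) nor glycolysis and fructose use (8 of 20 up, 5 down, camera adjusted p = 0.425) was called as a list. In insulin and growth factor signalling, 4 of 20 genes rose and 9 fell (camera adjusted p = 0.518). IGFBP1 (-1.07 ± 0.70), IGFBP3 (-0.55 ± 0.25) and ADIPOR2 (-0.47 ± 0.10) fell and TRIB3 (0.65 ± 0.43) rose. Of the urea cycle and amino acid breakdown genes, 7 of 28 rose and 14 fell (camera adjusted p = 0.223). The urea cycle genes ARG1 (-1.15 ± 0.27) and ASS1 (-1.08 ± 0.22) and TDO2 (-0.73 ± 0.20) of tryptophan breakdown fell, while PRODH (1.11 ± 0.13), proline dehydrogenase, rose.

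Interferon response genes rose, 15 of 21 with none lower (mean log2 ratio 0.40 ± 0.13, above 0 in 10 of 10 animals, camera adjusted p = 1.69e-04, adjusted p = 0.357 with an estimated correlation). The mean of this list was 0.60 with the software's processed signals and 0.56 with the authors' log2 ratios. USP18, RSAD2 (1.39 ± 0.47; well above background in the pool on 13 of 20 arrays), IRF7 (0.94 ± 0.34) and IFIT2 (0.52 ± 0.15) were higher in 10 of 10 animals. The acute phase list was lower, with 9 of 17 genes down and 2 up (mean log2 ratio -0.30 ± 0.21, below 0 in 9 of 10 animals, camera adjusted p = 0.0393, adjusted p = 0.748 with an estimated correlation). A2M (-1.44 ± 0.35), SAA3 and FGB (-1.17 ± 0.40), the fibrinogen beta chain, fell and the metalloreductase gene STEAP4 (1.53 ± 0.58) rose. The acute phase call was lost in 10 of 29 settings, the main one counted, while the list mean over all settings lay between -0.38 and -0.23. Besides the estimated correlation these were the strict filter (adjusted p = 0.0856), the mean of all probes (0.0964), eBayes with a trend and robust variance (0.0539), arrays with HFD in Cy3 (0.0742), the fits without animal 3, 6 or 8 (0.0725, 0.0543 and 0.0603), animals 5 to 10 (0.123) and the first scan session (0.0562). Complement and coagulation had 8 higher and 11 lower genes of 29 (camera adjusted p = 0.320), with SERPINC1 (-0.82 ± 0.35), antithrombin, F12 (-0.32 ± 0.09) and C1QA (-0.56 ± 0.30) lower. On the 14 arrays this list was called lower, at a mean of -0.08 (adjusted p = 0.0379), and on the 20 arrays adjusted p was 0.825 with an estimated correlation. Cytokines and chemokines were not called as a list (2 of 13 up, 5 down, camera adjusted p = 0.598). IL1B (0.39 ± 0.44) rose while CXCL9 (-0.69 ± 0.63) and CXCL12 (-0.15 ± 0.08) fell.

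Markers of hepatocytes were lower, 14 of 20 down and 2 up (mean log2 ratio -0.34 ± 0.09, below 0 in 10 of 10 animals, camera adjusted p = 0.00328, adjusted p = 0.357 with an estimated correlation). Besides ASS1 and FGB, AMBP (-0.79 ± 0.21) and AHSG (-0.65 ± 0.29), both secreted by hepatocytes, fell. The lists of bile acid synthesis (-0.33), PPAR alpha targets (-0.33), triglyceride synthesis (-0.32) and acute phase (-0.30) had means close to that of these markers, and whether a lower share of hepatocyte RNA contributes to them was not tested. Of the macrophage and Kupffer cell markers, 10 of 19 rose and 4 fell (mean log2 ratio 0.17 ± 0.13, above 0 in 9 of 10 animals, camera adjusted p = 0.205). LGALS3 (1.30 ± 0.37), CD68 (0.84 ± 0.34) and the Kupffer cell receptor CLEC4F (0.69 ± 0.20) rose and the scavenger receptor CD163 (-1.25 ± 0.32) fell. On the 14 arrays this list was called higher, at a mean of 0.26 (adjusted p = 0.0287), and on the 20 arrays adjusted p was 0.754 with an estimated correlation. No other cell type list was called. Camera adjusted p was 0.705 for stellate cells and fibroblasts (5 of 19 up, 7 down), 0.705 for endothelium (4 of 19 up, 5 down) and 0.425 for cholangiocytes (1 of 13 up, 4 down). It was 0.270 for T and NK cells (0 of 14 up, 5 down), 0.205 for B and plasma cells (1 of 9 up, 5 down), 0.425 for neutrophils (0 of 7 up, 3 down), 0.868 for erythroid cells (2 of 9 up, 3 down) and 0.683 for adipocytes (5 of 13 up, 3 down). The fibrillar collagen genes COL5A2 (0.48 ± 0.07) and COL1A1 (0.51 ± 0.22) and the crosslinking enzyme gene LOXL2 (0.53 ± 0.12) rose, within an extracellular matrix list of 7 higher and 9 lower of 31 (camera adjusted p = 0.982). Neither of the 2 further COL1A1 probes was called, and of the 8 further COL5A2 probes 2 were called higher and 1 lower, with a median of -0.023.

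Cytosolic ribosomal protein genes fell, 26 of 37 with 1 higher (mean log2 ratio -0.22 ± 0.11, below 0 in 10 of 10 animals, camera adjusted p = 8.40e-06, adjusted p = 0.748 with an estimated correlation), for example RPL32 (-0.69 ± 0.15), RPL10 (-0.66 ± 0.31) and RPS7 (-0.61 ± 0.18). Proteasome subunit genes fell, 14 of 24 with 2 higher (mean log2 ratio -0.23 ± 0.11, below 0 in 10 of 10 animals, camera adjusted p = 0.00694, adjusted p = 0.748 with an estimated correlation), PSMA6 (-1.01 ± 0.38) and PSMA7 (-0.66 ± 0.22) among them. In the unfolded protein and integrated stress response, 15 of 23 genes fell and 5 rose (mean log2 ratio -0.18 ± 0.15, below 0 in 9 of 10 animals, camera adjusted p = 0.0165, adjusted p = 0.753 with an estimated correlation). The chaperone genes DNAJC3 (-0.88 ± 0.37), DNAJB9 (-0.61 ± 0.19; well above background in HFD RNA on 14 of 20 arrays) and PDIA3 (-0.47 ± 0.15) fell and DDIT3 (0.67 ± 0.41), a stress-induced transcription factor, rose. On arrays with HFD in Cy3 alone the calls of the proteasome and of the stress response were lost (adjusted p = 0.190 and 0.118) at means of -0.28 and -0.21, and that of the stress response also in animals 1 to 4 (0.0508) at a mean of -0.07. Means on the 14 arrays were -0.16 for ribosomal proteins, -0.13 for the proteasome and -0.11 for the stress response. Autophagy and lysosome genes rose, 16 of 24 with 5 lower (mean log2 ratio 0.26 ± 0.11, above 0 in 10 of 10 animals, camera adjusted p = 0.0165, adjusted p = 0.748 with an estimated correlation), including the lysosomal hydrolase genes CTSA (1.16 ± 0.11), CTSB (0.79 ± 0.32) and CTSK (0.68 ± 0.28). This call was also lost with the mean of all probes (adjusted p = 0.0804) and in animals 5 to 10 (0.0613), at means of 0.20 and 0.21. Cell cycle genes rose, 16 of 28 with 3 lower (mean log2 ratio 0.14 ± 0.10, above 0 in 10 of 10 animals, camera adjusted p = 0.0397, adjusted p = 0.753 with an estimated correlation), with CDK1 (0.57 ± 0.27), CDKN3 (0.42 ± 0.17) and CCNB1 (0.25 ± 0.10) as examples. The mean of this list was 0.27 with the software's processed signals and 0.23 with the authors' log2 ratios. The cell cycle call was lost in 11 of 29 settings, the main one counted, while the list mean over all settings lay between 0.12 and 0.27. Besides the estimated correlation these were the fits with the animal or the slide as a random block (adjusted p = 0.0788 and 0.0725), the strict filter (0.0755), arrays with HFD in Cy3 (0.0900), the fits without animal 1, 2 or 9 (0.0738, 0.0709 and 0.0518), animals 5 to 10 (0.111) and the first and the later scan sessions (0.0983 and 0.0878). Adjusted over the list alone, the counts of all lists in this and the preceding paragraphs were as given, except for lower counts of 27 for ribosomal proteins, 15 for the urea cycle and 3 for T and NK cells. The exceptions also held 10 higher for the respiratory chain, 9 higher and 12 lower for complement, and 6 higher and 9 lower for stellate cells and fibroblasts.

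The arrays of a dye-swapped pair correlated across genes at a median Pearson r of 0.569 (range 0.521 to 0.670), where genes are not independent replicates. Arrays of opposite dye from different animals correlated at a median r of 0.489, with a range of 0.292 to 0.685. Averaged over each pair, the animals correlated with each other at a median r of 0.778. A dye effect, taken as the difference of each orientation from their mean, passed the same test for 6745 genes, with a median size of 0.0710 over all genes, and for 0 of them it was at least 2-fold, while the difference from one orientation to the other was at least 2-fold for 33, APOE and APOA2 among them. CROT (-0.33 with HFD in Cy5 and -1.16 in Cy3) and DNAJC3 (-0.48 and -1.28) also differed between the orientations. So did HSD17B13 (-0.67 and -1.37), ACLY (-0.62 and -1.26) and GPAM (-0.41 and -1.01). These genes are examples and not a full list. The arrays with HFD in Cy3 include the 6 that stood apart. The differences between orientations and the count of 6745 genes therefore mix a dye effect with the deviation of these arrays. Between the animals of these arrays and the other animals, the dye effect differed for 4731 genes. How much of the differences comes from the dyes alone was not tested. The first principal component of the arrays held 46.9% of the variance around the gene means and parted the 6 arrays from the other 14. Among the 6 arrays r lay between 0.838 and 0.926, and with the other 14 its median was 0.492.

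**Figure D4:**
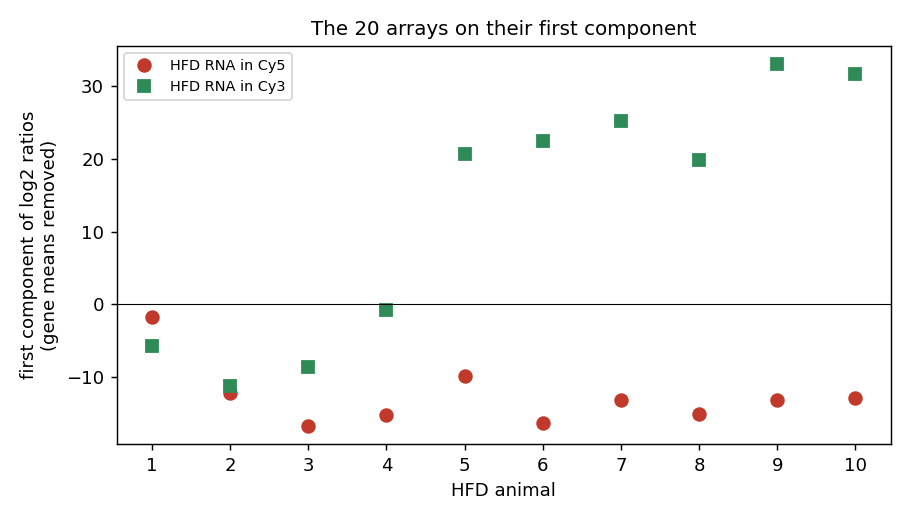
Position of the 20 arrays on the first principal component of their log2 ratios after removal of each gene's mean, by animal. Red circles hold HFD RNA in Cy5 and green squares in Cy3, and the squares of animals 5 to 10 lie above 0 while all other arrays lie below it.

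None of the 5 relations between gene lists across the 10 animals passed the adjusted threshold. The means of the lipid droplet and fatty acid synthesis lists had the largest correlation, with Pearson r = 0.663 (permutation p = 0.0347, adjusted p = 0.174) and Spearman rho = 0.479 (permutation p = 0.166). Without the 2 animals farthest from the median of the lipid droplet list r was 0.306. Leaving out extreme animals narrows the range and can lower r by itself, so this does not show that the relation rests on them. For lipid droplet with extracellular matrix r was 0.338 (permutation p = 0.339) and rho 0.394 (permutation p = 0.261), with r = 0.240 without 2 animals. With macrophage markers r was 0.461 (permutation p = 0.181) and rho 0.491 (permutation p = 0.154), with r = 0.516 without 2 animals. Fatty acid synthesis with cholesterol synthesis gave r = -0.163 (permutation p = 0.657) and rho = -0.127 (permutation p = 0.734), and r = 0.687 without 2 animals. Hepatocyte markers with extracellular matrix gave r = 0.388 (permutation p = 0.266) and rho = 0.406 (permutation p = 0.245), with r = 0.337 without 2 animals. Adjusted over the 5 relations, p was 0.423 for lipid droplet with extracellular matrix, with macrophage markers and for the hepatocyte relation, and 0.657 for fatty acid with cholesterol synthesis. For Spearman's rho the adjusted p was 0.734 for fatty acid with cholesterol synthesis and 0.326 for the other 4 relations. Because of the 6 arrays, r was also taken within animals 5 to 10. In the order above it was 0.813, -0.00398, -0.401, 0.170 and 0.235 (n = 6, exact permutation p = 0.0778, 0.992, 0.435, 0.718 and 0.651), and none was taken within animals 1 to 4, since correlations were taken only over at least 6 animals.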

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

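The tests of the livers of animals 5 to 10 and of slides and scan sessions were chosen after the result was seen. Values of single animals were compared with the other 9 by the gap to the nearest animal over the whole range, for 193 of the named genes, 48 list means and the agreement of the array pairs. Of these 242 measures, 6 had an animal far from the others. For independent measures taken without selection, chance would give about 1 in 20, or 12.1. The genes were selected by p, some also by the same sign in all animals, and overlap with the lists. The 6 found therefore cannot be set directly against 12.1.

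LIX1L was lowest in animal 10 at 1.58, against 1.79 to 1.93 in the others. AMACR was lowest in animal 10 at -0.60, against -0.39 to -0.15. SELS was highest in animal 2 at -0.18, against -0.56 to -0.36. ADIPOR2 was lowest in animal 7 at -0.72, against -0.54 to -0.36. TRIB3, a stress-induced regulator of insulin signalling, was highest in animal 7 at 1.68, against 0.18 to 0.91. The glutathione and oxidative stress defence list was below 0 only in animal 10, at -0.11, against 0.05 to 0.20 in the others.

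The 6 arrays with HFD RNA in Cy3 of animals 5 to 10 differed from the rest. The difference of animals 5 to 10 from animals 1 to 4 had a correlation across genes of -0.119 between the dye orientations, which argues against a difference of the livers themselves, since both orientations carry the same RNA. The slides of the 6 arrays held 10 other arrays, and all 3 scan sessions held at least 1 of the 6, which argues against slide and session, and the pool's red channel, whose own deviation (SD 0.155, against 0.334 in the green HFD channel) went partly with that of the HFD channel (r = 0.414), held a share of 0.0278 of the ratio's deviation, which argues against the pool's labelling as the whole cause. Of 100 splits of the animals into 4 and 6, 1, the real one, gave as many genes whose dye effect differs, 4731 against at most 2363 in the other splits, which decides nothing about chance, since this split was taken from the arrays that stood apart. The Cy3 labelling of these 6 HFD samples may be the source, a candidate explanation that stays untested because no label gives the labelling batches.

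Ribosomal protein and proteasome genes were lower in HFD liver. On the 14 other arrays the list means lay 0.18 and 0.14 below the median of all genes (differences of -0.18 and -0.14), with camera adjusted p of 1.34e-06 and 0.00459, and the shift was below 0 in 10 of 10 animals (-0.19 ± 0.09 and -0.18 ± 0.08 as means over animals), so that the 6 arrays do not account for it as a whole. On the 20 arrays both calls were lost with an estimated correlation (adjusted p = 0.748 for each). RNA quality and the diet itself stay open as explanations, untested, since the pool is 1 RNA.

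The genes that varied most between animals were more often below the pool. In the 10% of genes with the highest variance, 655 genes were lower and 415 higher, with a median log2 ratio of -0.15. A pool holds the arithmetic mean of its animals, which lies above the mean of logs. The slope of the mean log2 ratio on the variance across genes was -0.691, steep enough to count for this explanation by the bound set beforehand. Under equal spread in both diets the explanation gives a slope of -0.312. The fitted slope held only 1.8% of the variance of the mean ratios between genes. With equal spread, however, the explanation would give only -0.022 in these genes. In the next 10% of genes, where it gives -0.010, the median was 0.023. The variance used here includes measurement error, which does not raise a pool. Equal spread would therefore give no more than these 2 values in size. Whether a wider spread among the STD animals accounts for the rest cannot be told apart from a change by diet. The STD animals were not measured singly. All these values include the 6 HFD-in-Cy3 arrays of animals 5 to 10 that stood apart, and their share was not tested. In the fit on single arrays, 58 genes were at least 2-fold lower with the 6 arrays and 40 without them. For higher genes the counts were 45 and 50. A contribution of the 6 arrays to the lower ratios therefore also stays open.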

How the results depend on the processing

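The settings without 6 arrays, in part of the animals and within scan sessions were chosen after the data were examined. Over the settings fixed in advance the counts of higher and lower genes stayed within 1.5 times of 4343 and 3994: the exact sign-flip test gave 4225 and 3913, the animal as a random block 4443 and 4076, the slide 5041 and 4667, and leaving out an animal 4054 to 4496 and 3755 to 4050. The slide fit takes the 2 arrays of an animal as independent, so its larger counts overstate the number of replicates. Single genes were less stable than the counts: with the mean of all probes 6641 of the 8337 called genes kept their call and 301 were called in the opposite direction, on arrays with HFD in Cy5 5365 and 153, and on arrays with HFD in Cy3 6964 and 23. The first scan session gave 3914 and 3387 and the later ones 3187 and 2887. Quantile scaling of brightness leaves ratios unchanged by construction and tests nothing. No paired analysis was possible because there is 1 group. Of 199 named genes, 152 kept direction and call under all settings. CD3E and TFRC lost their calls in several fits without 1 animal.

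At least 2-fold, 45 genes were higher and 58 lower, but 104 and 113 with the software's processed signals, 85 and 92 with the authors' log2 ratios, 29 and 34 with the mean of all probes, 75 and 121 on arrays with HFD in Cy3, and 104 lower in animals 5 to 10. Of the lists, 3 higher and 11 lower by camera became 0 and 1 with an estimated correlation and 14 and 19 with fry, which does not compare a list with other genes. The mean of the cholesterol synthesis list went from -0.59 to -0.92 with the software's processed signals and -0.87 with the authors' log2 ratios, that of interferon response from 0.40 to 0.60 and 0.56, and that of cell cycle from 0.14 to 0.27 and 0.23. Arrays with HFD in Cy3 alone gave 4 lower lists, the 14 arrays 6 higher ones and animals 5 to 10 1 higher one. The 14 arrays, which still hold all 10 animals, gave 2529 lower genes. Animals 1 to 4 gave 2227 higher and 1614 lower, while animals 5 to 10 gave 4170 and 4048. How far the smaller number of arrays or animals accounts for the lower counts was not tested. With the mean of all probes the direction turned for CCR2 (0.081), COL14A1 (0.039), UGT1A1 (-0.026), PER1 (-0.18), RXRA (-0.10) and FLT1 (0.053), whose probes disagree. On arrays with HFD in Cy5 it turned for RBP4 (0.13) and AQP1 (0.055), on the 14 arrays for SGPL1 (0.028), CD3E (0.018) and TFRC (0.056), and in animals 1 to 4 for TFRC (0.062). With the 2 lists taken from opposite orientations, the relation of fatty acid to cholesterol synthesis had r = 0.310 one way and -0.404 the other, and that of lipid droplet to macrophage markers 0.411 and -0.149. Without 2 animals the former turned to 0.687. Except where stated, the cause was not tested. Genes not well above background in both channels on all 20 arrays rest on weaker signal, and without them 12522 genes were tested.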

Other observations

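The tests of the receptor and macrophage lists below used lists written after the leading genes had been seen. Genes of detoxification and lipid remodelling not described so far also changed. Of the cytochrome P450 and xenobiotic enzymes, 11 of 24 rose and 6 fell (mean log2 ratio 0.10 ± 0.09, above 0 in 9 of 10 animals, camera adjusted p = 0.320). CYP3A11 (0.91 ± 0.22; 2 of its 8 further probes were called higher) rose and UGT2B1 (-0.86 ± 0.22) fell. In glutathione and oxidative stress defence, 12 of 27 rose and 7 fell (mean log2 ratio 0.07 ± 0.08, above 0 in 9 of 10 animals, camera adjusted p = 0.425), with NQO1 (0.65 ± 0.11), GSTM3 (0.73 ± 0.38) and TXN1 (0.49 ± 0.13) higher. In phospholipid and choline metabolism, 11 of 19 rose and 5 fell (mean log2 ratio 0.13 ± 0.04, above 0 in 10 of 10 animals, camera adjusted p = 0.213), with ENPP2 (0.80 ± 0.12), which encodes autotaxin (median of its 10 further probes 0.26), and ETNK1 (0.56 ± 0.21) higher. On the 14 arrays without the 6 that stand apart, fitted as single arrays, the first and the last of these 3 lists were called higher (adjusted p = 0.0287 and 0.0434). The form of fit differs from the main one. All 20 arrays fitted in this form called 3 lists higher, interferon response and autophagy among them. The form of fit could therefore account for either of the calls on the 14 arrays, but not for both. On the 20 arrays the adjusted p of the P450 and the phospholipid list was 0.800 and 0.561 with an estimated correlation. In sphingolipid synthesis, 8 of 15 rose and 4 fell (camera adjusted p = 0.518), with SGMS2 (0.45 ± 0.13) higher.

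Among the selenoproteins, 7 of 16 rose and 7 fell, 8 adjusted over the list alone (camera adjusted p = 0.982), with TXNRD3 (0.63 ± 0.14) higher and DIO1 (-0.52 ± 0.33), a deiodinase, and SELK (-0.52 ± 0.28; -0.20 with HFD in Cy5 and -0.84 in Cy3) lower. In methionine and one-carbon metabolism, 8 of 20 rose and 7 fell (camera adjusted p = 0.982). SHMT1 (-0.86 ± 0.47), SHMT2 (-0.70 ± 0.29) and PEMT (-0.36 ± 0.12), which makes phosphatidylcholine, fell. Iron and haem metabolism had 7 higher and 8 lower genes of 21 (camera adjusted p = 0.982), with the ferritin gene FTH1 (0.66 ± 0.12; 1.07 with HFD in Cy5 and 0.25 in Cy3) and BLVRA (0.61 ± 0.28) higher and the iron exporter SLC40A1 (-0.60 ± 0.43) lower. Of the list for cytosolic heat shock, 1 of 12 genes rose and 5 fell (camera adjusted p = 0.205), with HSP90AA1 (-0.79 ± 0.48; median of its 2 further probes -0.20, and -0.33 with HFD in Cy5 and -1.24 in Cy3) lower. HSPD1 (-0.80 ± 0.41), which stands in this list although it encodes a mitochondrial chaperone, was lower too. The list mean was -0.18 on 20 and -0.05 on the 14 arrays. Retinol metabolism had 3 higher and 4 lower of 15 (camera adjusted p = 0.903), with RETSAT (-0.78 ± 0.19) lower. Steroid and sex hormone enzymes had 2 higher and 4 lower of 12 (camera adjusted p = 0.518), with SRD5A1 (-0.70 ± 0.27) lower. The circadian clock list had 4 higher and 4 lower of 18 (camera adjusted p = 0.982), with PER3 (0.46 ± 0.19) higher, and apoptosis and p53 had 5 and 5 of 19 (camera adjusted p = 0.868), with BAX (0.36 ± 0.12) higher. Adjusted over the list alone, the other counts of these lists were as given. The median, mean and test direction differed in sign for endothelium, erythroid cells, apoptosis, apolipoproteins, selenoproteins, methionine metabolism and iron, besides sterol transport.

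ABCG5, ABCG8 and SREBF1 rose while cholesterol synthesis genes fell, and all 3 are known targets of the liver X receptor. A hypothesis is that targets of this receptor rose as a group. A list of 19 other measured targets, 12 of which also stand in lists already tested, had 12 higher and 1 lower gene and a mean log2 ratio of 0.29, with camera p = 0.00192 and p = 0.0248 with an estimated correlation. MYLIP (0.87), LPL (0.81), APOE (0.69), MLXIPL (0.59) and ABCA1 (0.51) were higher in 10 of 10 animals. As given above, the rise of APOE came mainly from arrays with HFD in Cy5. Further probes gave a smaller rise for LPL and agreed only in part for ABCA1. The receptor's own gene NR1H3 was at -0.06 (adjusted p = 0.134). This is consistent with the hypothesis, although the targets also respond to other regulators.

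ANXA2, ANXA3 and LGALS3 rose in all animals. A hypothesis is that genes of lipid-associated macrophages rose as a group. A list of 17 such genes without LGALS3, 14 of which stand in other lists, had 7 higher and 3 lower genes and a mean of 0.14, with camera p = 0.122, which does not decide. CD63 (0.81), CTSB (0.79), GPNMB (0.64), CTSD (0.57) and TREM2 (0.35), the receptor that marks these cells, were higher in 10 of 10 animals, while PLIN2 (-1.01) and LIPA (-0.66) were lower. SPP1, an abundant gene of such cells, was at -0.0039 (adjusted p = 0.937), and most of the genes that rose are also expressed by other liver cells.

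The count of 8337 genes called was set against other sign patterns of the 10 animals. Of 100 patterns, 1, the real one, gave as many genes, and the highest of the others gave 6645 with 1 animal turned. This shows how far the animals agree and decides nothing about chance in the pool, which all 10 ratios share.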
